A study of Mus musculus with 13 samples.

How the data were processed

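Reduced representation bisulfite sequencing (RRBS), which reads cytosine methylation in the CpG-rich fraction of the genome released by a restriction enzyme, was used on genomic DNA of 13 mouse libraries. Per the labels, these were 2 female induced pluripotent stem cell (iPSC) libraries marked XaXa, 4 female iPSC libraries marked XO, 3 male iPSC libraries, 2 male mouse embryonic fibroblast (MEF) libraries, and 1 library each of male cells negative and positive for SSEA1, a surface antigen of mouse pluripotent cells. Feeder cells were removed from the iPSCs beforehand, per the labels' protocols. Nothing in the labels says which libraries came from separate cultures or lines, so the p-values measure only the spread between these libraries, part of which may be technical.

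The deposited tables list, for each CpG with at least 1 read, the count of all reads and the count of methylated reads, in total and for each strand, together with the methylated fraction, per the file headers. The counts deposited by the authors were not normalised. The fraction deposited by the authors equals methylated reads over all reads and was not used further. Reads were aligned with BSMAP to mm9, per the submitters' processing notes; the aligner's version, trimming and filters are not given in the sources used here. RRBS reads start at the enzyme's cut sites, so identical reads cannot be told from PCR copies, and intervals given here cover counting error only. The reads of a window are summed over its CpGs, so a read that spans several CpGs counts at each of them. The intervals treat these counts as separate reads and are therefore too narrow. Coordinates are those of the deposited tables (mm9), written from 1.

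Total reads over CpGs ranged from 4784488 in the library labelled XO 9 to 143148634 in XaXa 8. A methylation level is the percent of reads at a CpG that are methylated. The level of a library is the unweighted mean over autosomal CpGs with at least 10 reads in each of the 13 libraries, a set of 20653 CpGs, and 544 further CpGs gave the level of X. This set is limited by XO 9: without that library 62257 CpGs on autosomes and X have 10 reads. Levels of groups were compared with an exact two-sided permutation test of the difference of means over all splits of the libraries. The smallest p these splits allow is 0.0667 for XaXa against XO, 0.1 for XaXa against male iPSC and for male iPSC against MEF, and 0.0286 for XO against male iPSC, so only the last could pass 0.05.

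For regional changes, reads of the common CpGs were summed in 1 kb tiles with at least 3 of them (1352 tiles). A quasi-binomial model with 1 mean per group was fitted to methylated and unmethylated reads of the 11 libraries in the 4 groups with replicates, the dispersion was moderated across tiles as in limma (squeezeVar) and kept at 1 or above, and an F test was adjusted by the Benjamini-Hochberg method over all tiles. A tile counted as changed at an adjusted p under 0.05 and a difference of at least 10 percentage points. Deep libraries weigh more in this model, while group means given with an SD weigh libraries equally. On simulated data with the real read totals, 96 of 100 tiles changed by 20 points were recovered for XaXa against XO, 92 for XO against male iPSC and 58 for male iPSC against MEF, and all 100 tiles changed by 40 points in each of these comparisons; 5, 6 and 1 of the 1152 unchanged tiles were called. The simulation drew each tile on its own with a small set spread and changed only tiles of medium to high level. It gave no library a shift over the whole genome, while XaXa 7 and 8 differed as a whole, at 36.6% and 31.0%. These rates may therefore not hold for the real data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.

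Tests, alternatives, windows and the rule for named regions were set before the data were examined, with exceptions stated here. The rule names, for each comparison and direction, the 5 changed tiles with the largest difference (10 for XO against male iPSC) among those with at least 5 common CpGs and every library of one group above every library of the other, each imprinted window with at least 3 common CpGs, and each gene window. No imprinted window met this, so the imprinted windows named in the text come from the fixed list but were chosen after their values were seen. Windows for 21 imprinted control regions and for the promoters of Pou5f1, Nanog, Sox2 and Xist were placed at mm9 positions from general knowledge, not from an annotation, so a window can miss part of its region; the first and last CpG with reads are given. The planned level of the imprinted windows needed 3 CpGs with at least 10 reads in each library, and no window had them. The reported value therefore pools all reads of a window and takes the 17 windows with at least 10 reads in each library, which was decided after the data had been seen, as were the tests of single windows. The gene list promoters planned for comparison were not analysed here, because the gene table at hand has positions on another assembly (GRCm38.p6) and no mm9 annotation was used.

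Alternatives were a minimum of 5 or 20 reads, CpGs covered in the libraries compared, read-weighted levels, tiles of 300 bp or 5 kb, at least 5 CpGs per tile, a 20 point or no minimum difference, limma on log2 ratios of methylated and unmethylated reads with 2 added to each, a fit over the 2 groups compared, autosomes alone, other measures of X depth, XaXa against XO and male iPSC together, and each replicate left out in turn. Where a replicate left out leaves 1 library in a group, the model assumes that library to vary like the other groups. Alternatives added later left out libraries whose X depth differed from their label, took the CpG set without XO 9, capped depth at 200 reads and kept maternally methylated windows alone. Pairs of replicates correlated at levels between 0.898 and 0.961 across common autosomal CpGs, and no pair looked like a repeated library. The highest correlation of any pair was between groups, XO 6 with male iPSC 4 at 0.973, so replicates were not always closest to each other.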

Results

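CpG methylation was measured by RRBS in 13 libraries that follow male mouse fibroblasts through reprogramming to iPSCs and set male iPSCs beside female iPSCs labelled as carrying 2 active X chromosomes (XaXa) or a single X (XO). There were 2 XaXa, 4 XO and 3 male iPSC libraries, 2 male MEF libraries, and 1 library each of SSEA1 negative and SSEA1 positive male cells taken during reprogramming. Total CpG reads were 20259444 and 143148634 in XaXa 7 and 8, and 18830786, 25099122, 99546564 and 4784488 in XO 3, 5, 6 and 9. They were 19605073, 8042155 and 60276866 in male iPSC 1, 2 and 4, 11337174 and 25835728 in MEF 4 and 5, and 18064208 and 17312218 in the SSEA1 negative and positive libraries.

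Read depth on X and Y was used to check the labels. Relative to male iPSC libraries and to the autosomes, median X depth was 1.34 in XaXa 7 and 1.33 in XaXa 8, short of the 2 that a second X in all cells would give if depth followed copy number. Among libraries labelled XO it was 0.996 in XO 6, 1.12 in XO 5, 1.24 in XO 3 and 1.31 in XO 9. If depth followed copy number, the last 3 would go against a single X in all cells over the whole chromosome. Depth that varies between chromosomes stays open in XO 3 and 5, as given below. In the library labelled male MEF 5, X depth was 1.23 times that of MEF 4 and the SSEA1 libraries, and Y reads were 0.0219% of autosomal reads against 0.0913% in MEF 4 and 0.0397% to 0.0485% in the 6 female iPSC libraries. Of 268 Y-linked CpGs read in male and in no female iPSC library, 65 were read in MEF 4 and 18 in MEF 5. All libraries are therefore called by their label, XaXa included, and directions drawn from them carry that limit. The mean X to autosome read ratio was 1.09 ± 0.00859 (SD, n = 2) in XaXa, 0.938 ± 0.0936 (SD, n = 4) in the libraries labelled XO and 0.797 ± 0.0174 (SD, n = 3) in male iPSC. In exact two-sided permutation tests, p was 0.133 for XaXa against XO, 0.1 for XaXa against male iPSC and 0.0857 for XO against male iPSC. On the common CpGs alone the XO minus male iPSC difference in this ratio changed from 0.141 to -0.0256, and that of XaXa minus male iPSC from 0.293 to 0.126 (exact permutation p = 0.5). With depth capped at 200 reads per CpG these were 0.198 (exact permutation p = 0.0571) and 0.350 (exact permutation p = 0.1), and by median depth 0.138 and 0.237. For XaXa minus XO the difference was 0.152, with 0.151 on the common CpGs, 0.152 with capped depth and 0.0981 by median depth (exact permutation p = 0.533). The deepest CpG, on chromosome 2 at 98506660, held 240960 to 3924493 reads per library. The 3 deepest CpGs of a library held 4.97% (male iPSC 2) to 17.8% (XO 3) of its reads. Levels with CpGs weighted by their reads, given below, therefore lean on the deepest CpGs.

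**Figure D1:**
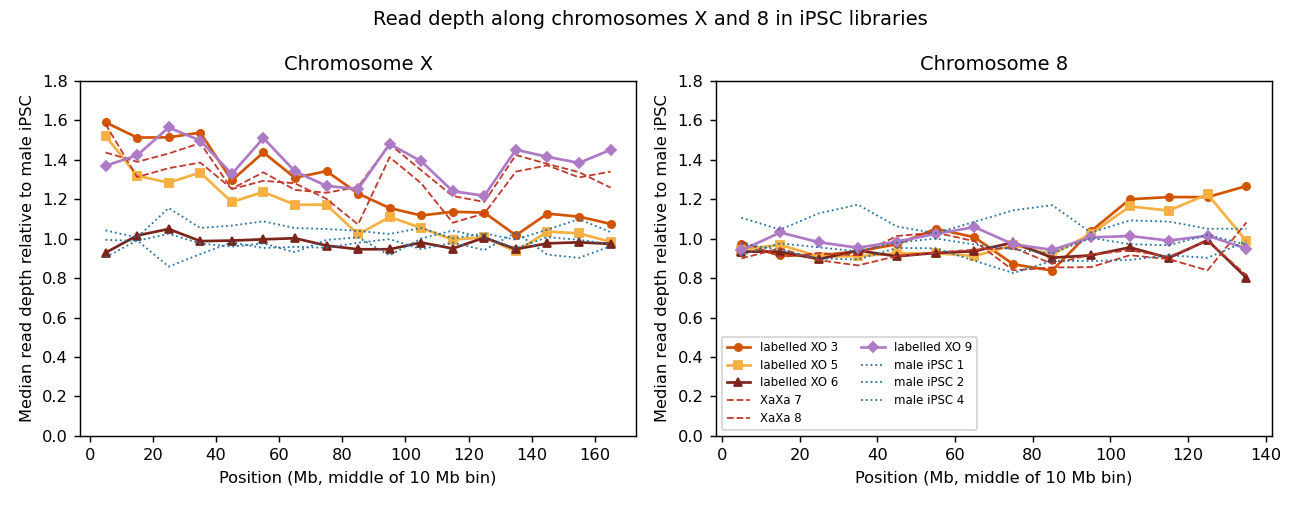
Median read depth in 10 Mb bins along chromosomes X (left) and 8 (right) relative to male iPSC libraries, against position in Mb; each line is an iPSC library. On X before 80 Mb depth was 1.44 in XO 3 and 1.28 in XO 5, and after 90 Mb 1.11 and 1.02, while XO 9 was at 1.41 and 1.38.

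The first comparison sets female iPSCs labelled with 2 active X chromosomes against those labelled with a single X. XaXa iPSCs were less methylated across the genome than the libraries labelled XO. The mean autosomal CpG level was 33.8% ± 3.95 (SD, n = 2) in XaXa and 55.4% ± 3.71 (SD, n = 4) in XO. This was a difference of -21.7 points, and both XaXa libraries (36.6% and 31.0%) lay below all XO libraries (50.04% to 58.5%). The exact permutation p was 0.0667, the smallest that 15 splits allow. The difference was negative on each of the 19 autosomes and on X, between -26.8 and -18.5 points. Of CpGs on autosomes, 0.668% ± 0.726 (SD, n = 2) were above 80% methylated in XaXa and 32.8% ± 7.50 (SD, n = 4) in XO, while 67.4% ± 2.24 (SD, n = 2) and 42.2% ± 5.39 (SD, n = 4) lay between 20% and 80%.

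**Figure D2:**
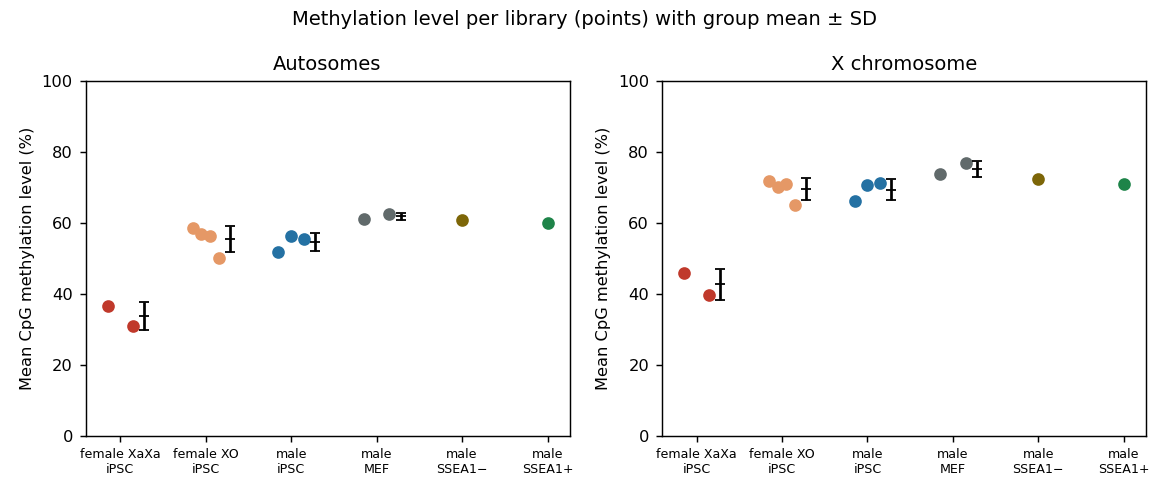
Mean CpG methylation level in percent on autosomes (left) and X (right) over CpGs with at least 10 reads in all 13 libraries; each point is a library and bars are the group mean ± SD. XaXa libraries sit between 31.0% and 36.6% on autosomes, and all other iPSC libraries at 50.04% or above.

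In the tile model, 728 of 1352 tiles were lower and 0 higher in XaXa than in XO, with 865 at an unadjusted p under 0.05 in either direction, and limma on log2 ratios called 620 lower and 0 higher. The mean level in XaXa was 0.604, 0.589 and 0.635 times that in XO in tiles under 20%, between 20% and 80%, and above 80% in MEFs. In the first of these classes XO 9 (2.63%) lay below XaXa 7 (2.78%; exact permutation p = 0.267 for the means). Of 495 tiles above 80%, 464 were lower, and of 533 under 20%, where the XO mean of 4.05% leaves most tiles no room for a 10 point difference, 26 were. In the CpG-densest tiles, with 40 or more CpGs read in any library, levels were 2.44% ± 0.565 (SD, n = 2) in XaXa and 4.22% ± 0.774 (SD, n = 4) in XO, and 11 of 245 were lower. The largest named difference was on chromosome 4 at 18407461 to 18407501, from 87.0% ± 1.804 (SD, n = 4) in XO to 47.5% ± 0.188 (SD, n = 2) in XaXa (adjusted p = 6.7e-06). Next came chromosome 3 at 121416450 to 121416484, from 71.9% ± 6.09 (SD, n = 4) to 32.9% ± 6.27 (SD, n = 2; adjusted p = 3.56e-06). Tiles on chromosome 15 at 94260681 to 94260716, chromosome 12 at 73521437 to 73521465 and chromosome 10 at 23546681 to 23546865 differed by -38.5, -38.0 and -37.6 points. Each of these 5 tiles had 5 common CpGs and at least 50 reads per library.

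The X chromosome was lower in XaXa too, at 42.8% ± 4.39 (SD, n = 2) against 69.5% ± 3.03 (SD, n = 4) in XO. In points, X exceeded the autosomes by less in XaXa than in XO, by 8.998 ± 0.434 (SD, n = 2) against 14.1 ± 0.895 (SD, n = 4; exact permutation p = 0.0667). As a ratio of X to autosome level the groups differed by less than the SD of either, at 1.27 ± 0.0185 (SD, n = 2) and 1.26 ± 0.0331 (SD, n = 4; exact permutation p = 0.667). With CpGs weighted by their reads the difference in points was -3.09 (exact permutation p = 0.667).

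Imprinted control regions, which keep methylation from a single parent and lie at intermediate levels in somatic cells, were low in XaXa. The windows placed for them had a mean of 48.9% in MEF, but some were not intermediate there. Nap1l5 was at 97.3% and 82.4% in MEF 4 and 5, from 37 and 102 reads summed over its CpGs. Plagl1 was at 0% and 42.3%, from 29 and 52 reads. These counts are low, so the levels are uncertain. Over 17 windows the mean level was 14.03% ± 3.85 (SD, n = 2) in XaXa and 26.4% ± 10.03 (SD, n = 4) in XO (difference -12.4 points, exact permutation p = 0.2). All 17 windows had a lower mean in XaXa. In the model, adjusted over the list alone, 7 fell, among them Nap1l5 on chromosome 6 (58856628 to 58857642), with 5.46% ± 1.57 (SD, n = 2) against 32.7% ± 19.9 (SD, n = 4; adjusted p = 0.000854), and Grb10 on chromosome 11 (11925589 to 11926884), with 9.25% ± 2.40 (SD, n = 2) against 31.9% ± 21.2 (SD, n = 4; adjusted p = 0.000986). Without XaXa 8, the deepest library, 0 of these 7 calls were left, while the difference went from -27.3 to -26.2 points at Nap1l5, from -22.6 to -20.95 at Grb10, from -21.5 to -8.87 at Plagl1 and from -18.3 to -8.15 at Peg13. Without XO 6, 5 windows were called and 12 of 17 differences were negative, with -17.5 points at Nap1l5 and -13.4 at Grb10, where the call was lost (adjusted p = 0.0694). Plagl1 was at -10.2 points without XO 3 and -34.1 without XaXa 7, and Peg13 at -28.4 without XaXa 7. Without XO 3 or without XO 5, 11 windows were called. The mean difference was -7.57 points without XO 6 (exact permutation p = 0.1), -7.04 at 5 reads per CpG (3 windows, exact permutation p = 0.667) and -5.27 over CpGs of the libraries compared (1 window, exact permutation p = 0.8). With XO 3 and 9 left out it was -15.9 points (exact permutation p = 0.333). With XO 3, 5 and 9 left out, which keeps only XO 6, whose X depth fits its label, it was -26.9 points. In XO 6 the relative depth of chromosome 11, which holds the Grb10 and Zrsr1 windows, was 1.30.

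**Figure D3:**
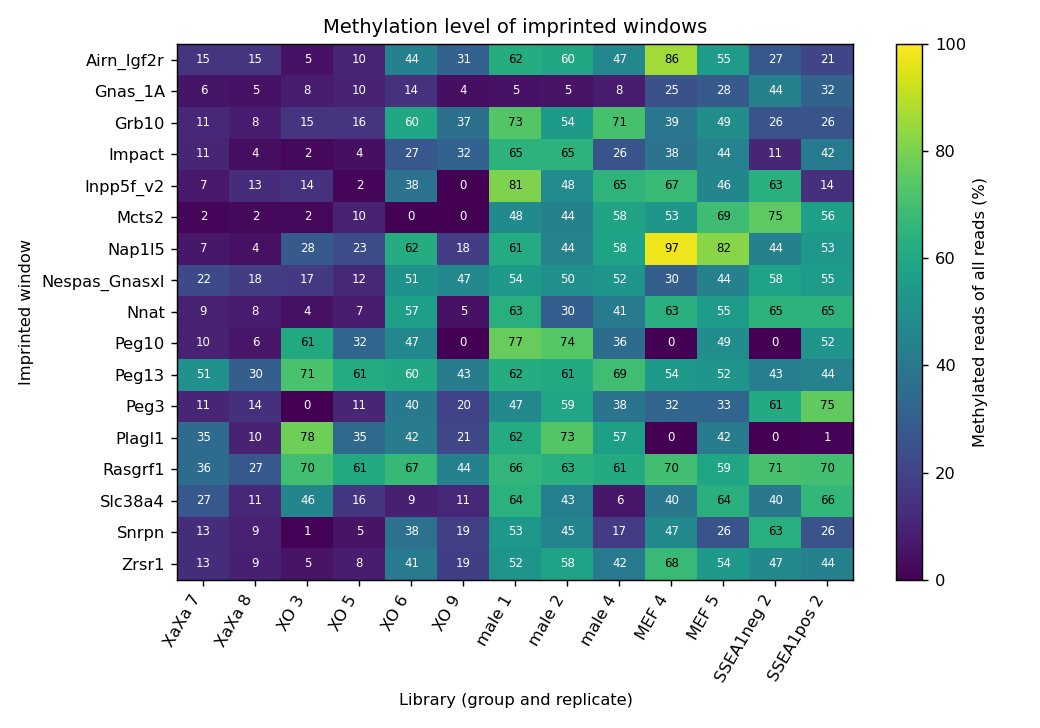
Methylation level in percent (colour and number) of 17 imprinted windows (rows) in 13 libraries (columns, group and replicate), from all reads of a window pooled. In the libraries labelled XO the mean over windows was 25.2%, 18.98%, 40.96% and 20.6% for replicates 3, 5, 6 and 9, against 44.2% to 58.4% in male iPSC.

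The second comparison sets XaXa iPSCs against male iPSCs, which have a single X and a Y. The male iPSC level was 54.6% ± 2.46 (SD, n = 3) on autosomes, so that XaXa differed by -20.9 points (exact permutation p = 0.1, the smallest that 10 splits allow), and both XaXa libraries were below all 3 male libraries. On X the male iPSC level was 69.4% ± 2.85 (SD, n = 3). X exceeded the autosomes by 14.8 ± 0.848 points (SD, n = 3) in male iPSC, a difference of -5.78 points for XaXa (exact permutation p = 0.1). As a ratio of X to autosome level they were at 1.27 ± 0.0185 (SD, n = 2) in XaXa and 1.27 ± 0.0160 (SD, n = 3) in male iPSC (exact permutation p = 0.8). With CpGs weighted by their reads the differences were -13.8 points on autosomes and -12.9 points in X minus autosome level. Of the 1352 tiles 690 were lower and 1 was higher in XaXa. The mean level in XaXa was 0.844, 0.602 and 0.631 times that in male iPSC in tiles under 20% (exact permutation p = 0.2), between 20% and 80%, and above 80% in MEFs. The largest named differences were the tile on chromosome 3 at 121416450, which was 80.7% ± 7.89 (SD, n = 3) in male iPSC and differed by -47.8 points in XaXa (adjusted p = 4.38e-06), and a tile on chromosome 2 at 83806677 to 83806715, with 87.2% ± 3.91 (SD, n = 3) in male iPSC and 43.3% ± 10.96 (SD, n = 2) in XaXa (adjusted p = 2.73e-06). Named tiles on chromosomes 12 (73521437), 4 (18407461) and 15 (94260681) differed by -40.8, -39.9 and -39.7 points. The single tile that was higher, on chromosome 11 at 96147493 to 96147867, was named after its values were seen and had 13.6% ± 2.08 (SD, n = 2) in XaXa and 2.17% ± 0.766 (SD, n = 3) in male iPSC; without XaXa 7 or without XaXa 8 the count of higher tiles was 0.

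The imprinted windows were at 51.4% ± 7.10 (SD, n = 3) in male iPSC, a difference of -37.4 points for XaXa (exact permutation p = 0.1). At 5 reads per CpG, which left 3 windows, it was -22.9 points (exact permutation p = 0.2), beside -21.8 points genome-wide. In the model 13 of 17 windows fell, adjusted over the list alone. Mcts2 on chromosome 2 (152512522 to 152513405) was at 1.89% ± 0.246 (SD, n = 2) in XaXa and 50.1% ± 7.51 (SD, n = 3) in male iPSC (adjusted p = 6.51e-05). Grb10, a growth factor receptor adaptor, differed by -57.0 points, Airn/Igf2r by -41.001 points and Zrsr1 by -39.3 points. The Gnas 1A window was low in both groups, with 5.25% ± 0.506 (SD, n = 2) and 5.91% ± 1.43 (SD, n = 3). Without XaXa 8, 0 windows passed the threshold with 1 XaXa library left, while all 17 differences stayed negative (Mcts2 -48.4 points, Grb10 -55.3 points).

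The third comparison, of the libraries labelled XO with male iPSCs, asks whether female iPSCs labelled with a single X differ from male iPSCs. Genome-wide levels were close. The difference was 0.815 points on autosomes (exact permutation p = 0.714) and -0.697 points in X minus autosome level (exact permutation p = 0.314), both smaller than the SD of either group, and the first changed sign without XO 3 (-0.190) or male iPSC 1 (-0.583). With CpGs weighted by their reads, where the deepest CpGs count most, the differences were 7.45 and -9.83 points (exact permutation p = 0.0571 for each). In tiles, 2 were lower and 5 higher in XO, with 200 at an unadjusted p under 0.05, and limma on log2 ratios called 0. The rule named 2 of them, on chromosome 6 at 47627601 to 47627781, with 46.7% ± 10.3 (SD, n = 4) in XO and 24.0% ± 2.54 (SD, n = 3) in male iPSC (adjusted p = 0.0215), and at 47636234 to 47636414, with 44.9% ± 9.43 (SD, n = 4) and 22.9% ± 1.71 (SD, n = 3; adjusted p = 0.0213). The other changed tiles were named after their values were seen. They differed by 24.0 points on chromosome 6 at 47601418 to 47601735, close to the named pair, by 17.5 points on chromosome 6 at 97902306 to 97902872 and by 16.9 points on chromosome 10 at 126789520 to 126789545. The lower tiles differed by -36.4 points on chromosome 10 at 83920404 to 83920431 and by -10.5 points on chromosome 4 at 133004220 to 133004255. The 3 close tiles on chromosome 6 reached 5116 to 6365 reads in a library, and the other changed tiles 498 to 920. The named pair also had equal length and 5 CpGs each, and whether these 3 are separate loci was not tested. Without male iPSC 4, or with a fit over these 2 groups alone, 0 tiles were called, and without XO 6 the number of higher tiles was 24. Of the 35 splits of these libraries into 4 and 3, 3 called at least 7 tiles, the real one included.

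Imprinted windows did not follow the genome-wide level. They were at 26.4% ± 10.03 (SD, n = 4) in the libraries labelled XO and 51.4% ± 7.10 (SD, n = 3) in male iPSC, a difference of -25.0 points with all XO libraries below all male iPSC libraries (exact permutation p = 0.0571, where 0.0286 is the smallest possible). It was -15.9 points at 5 reads per CpG (exact permutation p = 0.143) and -16.7 points over CpGs at 25% to 75% in MEF (exact permutation p = 0.114), each from 3 windows. The Snrpn window on chromosome 7 (67149466 to 67150115) was at 1.03% in XO 3 (95% Wilson interval 0.282 to 3.66), 5.14% in XO 5 (3.03 to 8.59), 37.8% in XO 6 (34.8 to 40.9) and 18.9% in XO 9 (9.48 to 34.2). It was at 53.2% (46.6 to 59.6), 45.2% (34.3 to 56.6) and 17.4% (14.5 to 20.7) in male iPSC 1, 2 and 4. Mcts2 fell in the model, at 3.16% ± 4.70 (SD, n = 4) against 50.1% ± 7.51 (SD, n = 3; adjusted p = 0.000199 over the list alone), and was the only window of 17 to do so. Without XO 6 the number was 11. XO 3, 5 and 9 had both the lower window levels and the higher X depth among the libraries labelled XO, and with those 3 left out, a choice made after seeing the data, the difference was -10.5 points.

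The fourth comparison describes reprogramming of cells labelled male, from MEFs to iPSCs. MEFs were at 61.9% ± 0.997 (SD, n = 2) on autosomes, so male iPSCs differed by -7.29 points (exact permutation p = 0.1, the smallest possible). With CpGs weighted by their reads the difference was -11.6 points (exact permutation p = 0.1). Of 1352 tiles, 259 were lower and 42 higher in male iPSC. The largest named loss was on chromosome 16 at 20177076 to 20177096, from 95.1% ± 2.86 (SD, n = 2) in MEF to 21.5% ± 1.63 (SD, n = 3) in iPSC (adjusted p = 1.43e-06). A pair of tiles followed on chromosome 4 at 145427110 to 145427367, from 78.3% ± 0.903 (SD, n = 2) to 7.87% ± 1.81 (SD, n = 3; adjusted p = 1.8e-07), and at 145722462 to 145722722, with a difference of -68.0 points. Tiles on chromosome 5 at 150357490 to 150357801 and chromosome 6 at 56197325 to 56197360 differed by -53.5 and -49.1 points, the last with an adjusted p of 0.0609 without MEF 5. The gain named by the rule was on chromosome 19 at 7049884 to 7049923, from 2.35% ± 1.15 (SD, n = 2) to 18.9% ± 5.598 (SD, n = 3; adjusted p = 0.042, and 0.0631 when fitted over these 2 groups alone). Its adjusted p was 0.181 without MEF 4, 0.228 without MEF 5 and 0.062 without male iPSC 2. Imprinted windows were at 48.9% ± 1.73 (SD, n = 2) in MEF and 51.4% ± 7.10 (SD, n = 3) in iPSC (exact permutation p = 0.7). Gnas 1A was the window that fell, from 26.4% ± 2.30 (SD, n = 2) to 5.91% ± 1.43 (SD, n = 3; adjusted p = 0.00112 over the list alone), with a difference of -20.5 points. Without male iPSC 4 it was -21.4 points, at an adjusted p of 0.0769. The iPSC libraries and the fibroblast and SSEA1 libraries differed in the CpGs they covered with at least 5 reads. Median overlap was 0.319 across these sets (0.200 to 0.390) against 0.564 (0.181 to 0.833) and 0.518 (0.456 to 0.588) within them. The lowest iPSC pair was XaXa 8, the deepest library, with XO 9, the shallowest, so overlap may also depend on depth. Library preparation and cell type cannot be told apart here, and without the library labelled MEF 5 the losses numbered 124. The gains numbered 24 without MEF 4, 27 without MEF 5 and 25 without male iPSC 4.

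The SSEA1 negative and positive cells stayed near the fibroblasts. Autosomal levels were 60.7% in SSEA1 negative and 59.9% in SSEA1 positive cells, with 1 library each and no test. In the 259 tiles that were lower in male iPSC, mean levels were 69.2% and 70.6% in the MEF libraries, 68.7% in SSEA1 negative cells, 67.7% in SSEA1 positive cells and 30.1% to 35.1% in male iPSC. In the 42 tiles that were higher, they were 33.8% and 41.2% in MEF, 39.4% and 35.5% in the SSEA1 negative and positive cells, and 64.6% to 67.7% in male iPSC. These tiles were chosen by their MEF and iPSC levels, so chance in that choice also shifts the gap of each group to the SSEA1 libraries.

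Gene windows were described without a test, with 95% Wilson intervals. In the Sox2 window, around a pluripotency factor gene on chromosome 3 (34547001 to 34550708), levels were 21.3% (18.2 to 24.8), 23.8% (21.4 to 26.3), 15.8% (14.7 to 16.99) and 42.4% (32.8 to 52.6) in XO 3, 5, 6 and 9. The highest level in XaXa and male iPSC was 2.48% (1.39 to 4.39), in male iPSC 1, and MEF 4 and MEF 5 were at 0.752% (0.206 to 2.70) and 7.17% (5.48 to 9.33), and SSEA1 negative and positive cells at 9.05% (6.69 to 12.1) and 4.36% (2.95 to 6.41). In the Pou5f1 window, at the gene of the pluripotency factor Oct4 on chromosome 17 (35641894 to 35644996), levels were 41.7% (34.9 to 48.9), 24.5% (19.8 to 30.0), 22.6% (19.9 to 25.5) and 15.6% (7.75 to 28.8) in XO 3, 5, 6 and 9, and 1.802% (0.496 to 6.33) and 3.17% (2.33 to 4.31) in XaXa 7 and 8. They were 23.6% (21.9 to 25.4), 32.9% (29.8 to 36.2) and 2.53% (1.45 to 4.36) in male iPSC 1, 2 and 4, from 2241, 829 and 475 reads. A segment that overlaps this window had 18.6, 17.04 and 1.08 times the mean read depth of the female iPSC libraries there, so the levels of male iPSC 1 and 2 come largely from excess reads. MEF 4 and MEF 5 were at 32.4% (19.6 to 48.5) and 58.1% (55.1 to 61.1), and SSEA1 negative and positive cells at 46.96% (43.4 to 50.6) and 51.8% (48.5 to 55.1), with segment depths of 0.516, 6.73, 7.21 and 8.43. The windows placed for Nanog and Xist held no reads.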

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

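The tests of depth between chromosomes, of XaXa libraries under a wrong label, of position along X, of the genome-wide level and of the flanks of Pou5f1 were chosen after the results they bear on were seen, as were all values of chromosome depth given here.

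Relative X depth above male iPSC in the libraries labelled XO 3, 5 and 9 (1.24, 1.12 and 1.31) was weighed first; whether XO 3 and 5 come from 1 line or from separate lines is not stated, which bears on n = 4 for XO. The CpG density and level of X are argued against, since the lowest of the 3 stayed at 1.11 after scaling within such classes while the highest male iPSC library was at 1.05; depth that varies between chromosomes is argued against in XO 9, whose highest autosome was at 1.02, and stays open in XO 3 and 5, where distal chromosome 8 was at 1.21 and 1.18, the latter above the X depth of XO 5, and at 1.28 and 1.26 times its proximal part. A gained part of X could not be decided over all 3 by the share of X bins above the autosomal range, which was 52.9% at its lowest and 100% in XO 9. Depth of X before 80 Mb over after 90 Mb, relative to XaXa, was at least 1.22 in XO 3 and 5 and at most 1.06 in the other iPSC libraries. X depth after 90 Mb was 1.11 in XO 3 and 1.02 in XO 5, against 1.33 and 1.28 in XaXa 7 and 8. Depth along chromosome 8 varied about as much in XO 3 and 5, while its distal part was at 0.940 to 1.04 times its proximal part in the other iPSC libraries. Uneven depth and gained parts were not told apart. This X ratio therefore does not decide on a second whole X or a wrongly labelled XaXa library in XO 3 and 5. XO 9 was at 1.01, as a second whole X in all or part of its cells would give. A single X would give the same, with XO 6 at 1.02 and male iPSC at 0.981 to 1.04, so this ratio alone does not show a second X. The X depth of XO 9 after scaling, 1.28, lay within that of XaXa (1.25 and 1.29). Its Sox2 window at 42.4% (32.8 to 52.6) lay above XaXa 7 and 8 at 1.48% and 0.758%, as did its autosomal level of 50.04%, the outcome compared. A wrong label therefore stays open in XO 9.

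Imprinted windows that were lower in the libraries labelled XO than in male iPSC were weighed next. A lower level over the whole genome is argued against by the genome-wide difference of 0.815 points beside -25.0 points in the windows. For intermediate level and CpG density, 5693 other tiles were drawn on, at 25% to 75% in both MEF libraries and with at least 10 CpGs seen. The lowest mean difference in 10000 random sets of them was -5.89 points, beside -26.3 points in the maternal windows. The share as low was 1e-04, the smallest such sets can give. Such tiles did not share the difference. The windows were not held to that range, with Mcts2 inside it (53.1% and 68.8% in MEF) and Nap1l5 outside (97.3% and 82.4%). Density was held only to that minimum, so level and density are not excluded. For counting error, up to 12 of 16 maternal windows had an interval wholly below those of all male iPSC libraries in an XO library. There were 11 in XO 3, 12 in XO 5, 2 in XO 6 and 7 in XO 9. These intervals count a read at each CpG it spans and are too narrow, so they do not exclude counting error. The sex of the cells, the X depth of XO 3, 5 and 9 and their culture history stay open, and the design does not part them.

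Read depth on chromosome 17 in a segment from 35644001 on, around Pou5f1, relative to female iPSC, was 18.6 in male iPSC 1, 17.04 in male iPSC 2, 6.73 in MEF 5, 7.21 in SSEA1 negative and 8.43 in SSEA1 positive cells, and 1.08 in male iPSC 4 and 0.516 in MEF 4. The depth of the surrounding part of the chromosome is argued against, since the 1 Mb flanks reached at most 1.19 in any library. Extra copies of this segment, as in a reporter or transgene, may be a candidate source, and no biological explanation was tested.

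In 29 tests of the 4 libraries labelled XO, 3 had a library far from the others, and chance alone gives about 1 in 20 such groups. The Nnat window was at 56.6% in XO 6, the tile on chromosome 12 at 73521437 at 66.0% in XO 9, and the tile on chromosome 6 at 47627601 at 62.0% in XO 3. Relative depth of chromosome 11 was 1.30 in XO 6 and that of chromosome 8 was 1.17 in male iPSC 4. Relative X depth was 1.23 in the library labelled male MEF 5.

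The 7 tiles called between XO and male iPSC were set beside all splits of these 7 libraries into 4 and 3. Of 35 splits, 3 gave as many, the real one included, and the highest other split gave 11, so chance is not excluded for this count.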

How the results depend on the processing

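Alternatives chosen after the data were seen are those that left out XO 3 and 9 or XO 3, 5 and 9 together, took the CpGs of the libraries other than XO 9, capped depth or kept maternal windows, and the pooled windows themselves. Of 310 alternative values of levels, read ratios and counts, 226 were unchanged, 6 newly passed the threshold, 71 moved and 7 changed sign. The 6 came from XaXa set against XO and male iPSC together, a different comparison, with each test counted under both XaXa comparisons. Unchanged levels and read ratios kept their direction and side of the threshold. The splits of 2 groups allow a p under 0.05 only for XO against male iPSC with all libraries. Elsewhere the side was fixed in advance, so only the direction could change. Unchanged counts of tiles stayed near the main count in size, and no measured spread was used. Of 526 for single tiles and windows, 447 kept direction and side, 36 no longer passed, 23 newly passed and 20 changed sign. Except where a smaller or larger CpG set, a different threshold or fewer libraries by construction changed how many tiles could be called, the cause was not tested. No paired analysis was possible because no 2 groups compared share 2 or more replicate numbers. The gene list promoters and their alternatives were not run, and at least 20 reads per CpG gave no imprinted window. Depth limits the common set, which XO 9 narrows most.

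With XaXa set against XO and male iPSC together, the differences were -21.3 points in genome-wide level, -5.38 points in X minus autosome level and 0.213 in read ratio, each with an exact permutation p of 0.0278; the X to autosome level ratio of XaXa was not shown to differ from either group (exact permutation p = 0.667 and 0.8). The genome-wide difference kept its sign in all settings run except XO minus male iPSC, which ranged from -0.583 to 2.62 with single libraries left out and reached 7.45 with CpGs weighted by reads. The read ratio difference over the common CpGs was -0.0256 for XO minus male iPSC and 0.126 for XaXa minus male iPSC, beside 0.198 and 0.350 with capped depth and 0.138 and 0.237 by median depth; for XaXa minus XO it was 0.0981 by median depth beside 0.152. The male iPSC minus MEF difference of the imprinted windows was -7.30 points at 5 reads per CpG (3 windows), -1.96 over CpGs covered in the libraries compared (2 windows) and -3.73 over CpGs at 25% to 75% in MEF (3 windows), and -0.988 to 6.11 with single libraries left out.

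Tiles lower and higher in XaXa than in XO were 6963 and 2 at 5 reads, 2692 and 2 over CpGs of the libraries compared, and 3068 and 2 over the CpG set without XO 9, 19 lower at 20 reads, 42 lower with 5 CpGs per tile, 7 higher with no minimum difference, and 3 higher without XO 3, 5 and 9. Against male iPSC they were 6505 and 18 at 5 reads, 18 and 0 at 20 reads, 17809 and 34 over CpGs of the libraries compared, 39 and 0 with 5 CpGs per tile, and 2835 and 10 over the CpG set without XO 9. The higher tiles were 0 with 300 bp tiles and with a 20 point minimum, 13 with no minimum, 4 in a fit over the 2 groups, and 0 to 3 with single libraries left out.

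For XO against male iPSC, lower and higher tiles were 0 and 0 with limma, at 20 reads and in a fit over the 2 groups, 11 and 77 at 5 reads, 8 and 16 over CpGs of the libraries compared, 1 and 2 with 300 bp tiles, 4 and 15 with 5 kb tiles, 0 and 2 with 5 CpGs per tile, 1 and 3 with a 20 point minimum, and 8 and 12 without XO 3, 5 and 9. There were 36 higher over the CpG set without XO 9 and 1 lower without XO 3 and 9. With single libraries left out, lower tiles were 0 to 5 and higher tiles 0 to 24, the ends being male iPSC 4 and 1 and male iPSC 4 and XO 6. For male iPSC against MEF they were 2364 and 543 at 5 reads, 14 and 2 at 20 reads, 1469 and 331 over CpGs of the libraries compared, and 24 and 0 with 5 CpGs per tile. With single libraries left out, lower tiles were 124 (MEF 5) to 276 and higher tiles 24 (MEF 4) to 47.

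Single windows changed sign with single libraries left out. For XaXa minus XO the ranges were -2.32 to 1.03 points at Mcts2, -14.6 to 2.84 at Nnat, -11.3 to 2.09 at Peg3, -9.59 to 2.68 at Snrpn, -8.17 to 4.41 at Inpp5f, -11.4 to 0.602 at Zrsr1 and -9.50 to 7.15 at Slc38a4. For XaXa minus male iPSC the range was -1.12 to 0.159 at Gnas 1A. For XO minus male iPSC the ranges were -6.27 to 2.36 at Rasgrf1 and -9.50 to 0.123 at Peg13. For male iPSC minus MEF they were -6.30 to 4.54 at Rasgrf1, -8.70 to 12.7 at Snrpn, -2.60 to 18.5 at Inpp5f, -27.2 to 1.73 at Slc38a4 and -29.8 to 0.740 at Airn/Igf2r.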

Other observations

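The CpG-densest tiles, with 40 or more CpGs read in any library, had a low level in each library and were lower in male iPSC than in fibroblasts, at 2.91% ± 0.198 (SD, n = 3) and 8.57% ± 0.533 (SD, n = 2), with 31 of 245 tiles lower and 2 higher in the model (exact permutation p = 0.1 for the means, the smallest possible). SSEA1 negative and positive cells were at 7.81% and 7.89%. In XO the level was 4.22% ± 0.774 (SD, n = 4), a difference of 1.32 points from male iPSC (exact permutation p = 0.0571). In tiles above 80% in fibroblasts, male iPSC were at 71.7% ± 3.37 (SD, n = 3) against 89.1% ± 0.333 (SD, n = 2), with 144 of 495 lower, a class chosen by its fibroblast level.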
